A study of Homo sapiens with 4 samples.

How the data were processed

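The series measured how 4 HIS-tagged human transcription factors made in E. coli bound double-stranded DNA printed on glass, with 1 array per protein and fluorescence read at 635 nm from an Alexa647 label. The proteins were full-length KLF3, residues 31 to 264 of FOXO3A, residues 142 to 269 of FOXA2 and residues 1 to 114 of IRF1. KLF3 and IRF1 were bought, per the labels. Protein concentrations, incubation and washing were not given in the sources used here.

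Per the file headers, the deposited scanner tables held for each spot a median foreground intensity and a local background intensity at 635 nm, their difference, and the percent of pixels at the scanner's ceiling. The deposited values used here were normalized intensities. The normalization was not stated; it was worked out from the values themselves. In 100% of spots with a value, the deposited intensity equalled the foreground intensity divided by the median of the 9 by 9 block of spots around it and multiplied by the median of the whole array, within a tolerance of 0.001. The deposited intensity was therefore not background-subtracted, and a fold change computed from it is smaller than the same fold in bound protein, by an amount that depends on the background of that array. The table of the whole series held the same intensity for 20250 of 20250 spots on each array. Spots that the authors had marked as bad, and control spots, had no deposited intensity.

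Each array had 20250 spots in 135 rows and 150 columns, of which 19500 carried test sequences and 750 were control spots. Test sequences were 60-nt hairpins, so that each oligonucleotide folded into a duplex holding a site of 11 or 12 base pairs. There were 750 printed names with 26 spots each. Because 94 sequences had been printed under several names, spots were pooled by sequence, which gave 627 distinct sequences, 344 of them with at least 1 methylcytosine and 252 with exactly 1. Sequences are given below as the top strand and, where needed, the bottom strand, each read from its 5′ end, with X for 5-methylcytosine; positions are counted from 1 at the 5′ end of the top strand. In 1 sequence a misplaced methylcytosine left the strands unpaired, and that sequence was left out. The sites were taken from the printed sequences; genome positions were not given in the sources used here.

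Each variant was compared with the same sequence lacking the change. A single-base mutation was compared with its reference site, and a sequence with methylcytosine was compared with the identical unmethylated sequence. This gave, on each array, comparisons of 233 mutations, 106 methylcytosines outside CpG, 142 CpGs methylated on 1 strand, 64 CpGs methylated on both strands and 17 sequences with several methylcytosines. Methylcytosine outside the binding site was not analysed here, because no printed sequence of that kind was found. Intensities were log2 transformed, and the spots of the variant were compared with those of its reference in limma 3.58.1 under R 4.3.3, with moderated variances and Benjamini-Hochberg adjustment within each class and array. A comparison was tested where the mean log2 intensity of variant and reference together lay above the 95th percentile of the 30 randomized control sequences of that array, and it was called at an adjusted p under 0.05. Of these 30 controls, 14 carried methylcytosine, so the background was not set by unmethylated sequences alone. Errors of log2 differences are standard errors over spots, and fold changes come from means of log2 intensities, while levels are medians over spots. No value was carried from one array to another except in the contrast between FOXO3A and FOXA2, which was tested in limma on the difference of the 2 methylation effects.

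The tests, the filter, the classes, the motif strings and the rule for naming sequences were fixed before the data were examined. The rule named, per protein and class, the 4 called comparisons with the largest rise and the 4 with the largest fall, the reference sites of the protein, the 3 brightest reference sites on each array, and up to 4 differences between the FOX proteins in each direction. Other sequences are named as chosen after their values were seen. Methylcytosine was compared with thymine by Pearson and Spearman correlation across positions of the protein's own family, with p from 100000 permutations and Benjamini-Hochberg adjustment over 12 Pearson correlations. Those correlations used all positions, bound or not, and 10000 swaps of substitution labels tested whether thymine correlated more closely than adenine or guanine. The percent of IRF1 signal kept above the median of the controls, with 95% intervals from 2000 bootstrap draws of spots, was added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for everything outside limma.

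Alternatives fixed in advance were a Mann-Whitney test on spots, a further limit of 1.5-fold, no filter on binding, a filter at the 99th percentile of the controls, foreground intensity without spatial correction, normexp background correction with an offset of 50, a 5 by 5 window, a variance trend, leaving out 1 random spot per sequence, and the table of the whole series. Alternatives added after the data had been seen were leaving out spots with saturated pixels or with background above foreground, analysing the upper and the lower part of the arrays separately, and separate reference spots for the methylcytosine and thymine effects. The fit was tested on simulated data made from the 329 methylation comparisons of each array without the filter, with 200 of them changed. Among the 129 unchanged ones the share called was 3.10% for KLF3, 3.10% for FOXO3A, 3.88% for FOXA2 and 2.33% for IRF1. A change of 0.1 on the log2 scale was recovered in 88.2% of cases for KLF3, 75.6% for FOXO3A, 60.3% for FOXA2 and 81.4% for IRF1, and a change of 0.3 in 98.4% for IRF1 and 100% for the others. Unchanged pairs were simulated with 1 shared mean, so these shares cover spread between spots and not other differences in brightness between sequences. In the data without the filter, methylation calls at sites of other families reached 29.8% for KLF3, 11.7% for FOXO3A, 0% for FOXA2 and 0.45% for IRF1.

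With n = 1 array per protein, every p-value covers only the spread between spots of that array. Differences between proteins cannot be separated from differences between arrays, and their number limits the precision.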

Results

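Binding of 4 human transcription factors was measured on arrays of DNA hairpins that carried known binding sites, all single-base changes of those sites, and methylcytosine at CpG and at other positions. The factors were FOXA2 and FOXO3A, which share the forkhead DNA-binding fold, IRF1, an activator of interferon-responsive genes, and KLF3, a zinc-finger repressor. Each protein had n = 1 array, so there were no replicate arrays. A sequence was represented by a median of 24 spots with a value for FOXA2, 26 for FOXO3A, 26 for IRF1 and 23 for KLF3. The 7 reference sites comprised 3 forkhead sites (ATGTAAACAAC, ATGCAAACAAC and ATGTAACCAAC), 2 interferon-response sites (CGAAAGCGAAAC and CGAAAGTGAAAC) and 2 sites printed for KLF3 (GACCACGCCCA and GACCGCGCCCA). Median foreground against local background intensity was 3384 against 2233 for FOXA2, 4761 against 1970 for FOXO3A, 536 against 510 for IRF1 and 7680 against 6062 for KLF3. Positions are counted from 1 at the 5′ end of the top strand, X is methylcytosine, and a second sequence after a slash is the bottom strand. KLF3 had values at 16773 of its 19500 test spots and FOXA2 at 17892, while both other arrays had values at 19500.

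The first question was which reference sites each protein bound above the background of randomized sequences. IRF1 bound both interferon-response sites far above the controls and no other reference site. FOXA2 bound ATGTAAACAAC most strongly and ATGCAAACAAC more weakly, and FOXO3A bound ATGTAAACAAC. GACCGCGCCCA, printed for KLF3, also passed the 95th percentile of the controls on both forkhead arrays. KLF3 passed the 95th percentile of the controls at neither of its own sites.

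For IRF1, CGAAAGTGAAAC had a median intensity of 2134.21 and a log2 level of 11.06 ± 0.74 (SD, n = 78 spots), 4.04-fold over the median of 527.684 for the 30 controls. CGAAAGCGAAAC reached 1866.72, with a log2 level of 10.87 ± 0.65 (SD, n = 130 spots), which was 3.54-fold over the controls. The other 5 reference sites lay between 0.989-fold and 1.01-fold of the control median on that array. For FOXA2, ATGTAAACAAC reached 4813.91 (log2 12.23 ± 0.18, SD, n = 67 spots), 1.52-fold over the controls and brighter than 30 of 30 of them. ATGCAAACAAC reached 3722.75 on the FOXA2 array, brighter than 29 of the 30, whereas ATGTAACCAAC reached 3036.51 and exceeded 11 of them. For FOXO3A, ATGTAAACAAC reached 5724.17 (log2 12.48 ± 0.22, SD, n = 78 spots), 1.33-fold over the control median of 4316.94 and brighter than 29 controls. ATGCAAACAAC exceeded 26 controls on that array. The GC-rich site GACCGCGCCCA was as bright on the FOXO3A array (5767.57) as the forkhead site and lay just above the 95th percentile of the controls on the FOXA2 array (3709.56). On the KLF3 array, GACCACGCCCA reached 9856.88 and exceeded 27 of 30 controls, and GACCGCGCCCA reached 8681.73 and exceeded 26.

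The comparison with controls is a rank on 1 array and carries no p-value. Intensity rose with the GC content of the 30 controls on 3 arrays, with a Pearson r across sequences of 0.89 for FOXO3A, 0.80 for FOXA2 and 0.58 for KLF3, and 0.054 for IRF1. Spearman's rho was 0.88, 0.77, 0.78 and 0.026 in the same order, and the permutation p of r was 1e-05, 1e-05, 0.00033 and 0.778 (1e-05 being the smallest these permutations can give; for rho 1e-05, 1e-05, 1e-05 and 0.891), or 2e-05, 2e-05, 0.00044 and 0.778 after adjustment over the 4 arrays. With the 2 sequences farthest from the median left out, r was 0.90, 0.79, 0.61 and 0.14. Under the 99th percentile of the controls, with foreground intensities or with normexp correction, 0 reference sites passed for FOXO3A and 1 for FOXA2.

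**Figure D1:**
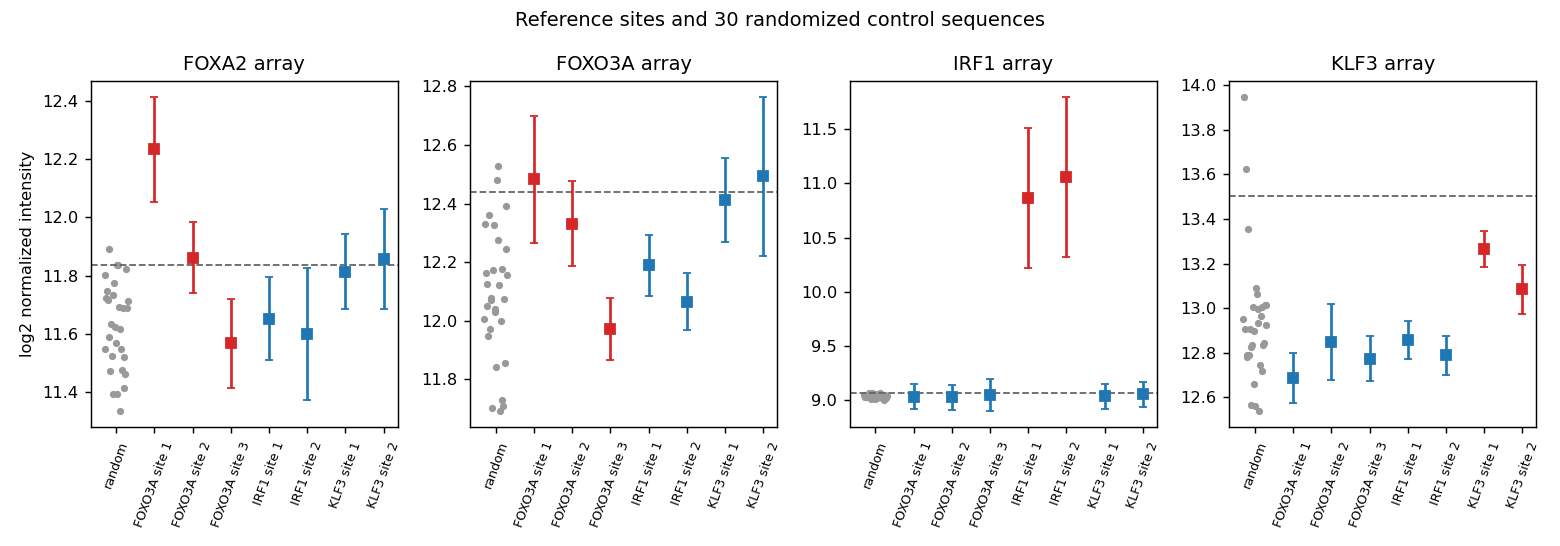
Log2 normalized intensity of the 30 randomized control sequences (grey points, medians over spots) and of the 7 reference sites (squares, median with the SD over spots; red, sites of the protein's own family; blue, other sites) on each array, with the 95th percentile of the controls dashed. Both interferon-response sites stood far above the controls on the IRF1 array, at 1866.72 and 2134.21.

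The second question was how single-base changes altered binding. In IRF1, changes of positions 3 to 5 and 8 to 11, within the GAAA repeats, removed most of the binding, while changes of position 2, the first base of the first repeat, left part of it. Between the repeats, position 6 tolerated change in CGAAAGCGAAAC but not in CGAAAGTGAAAC, and most changes of position 7 lowered binding in both. In CGAAAGTGAAAC, A5C brought the intensity from 2134.21 to 528.437, the level of the controls, a log2 change of -2.09 ± 0.10 (SE, n = 52 and 78 spots; limma adjusted p = 1.86e-40). G8T (-2.08 ± 0.14), G8C (-2.07 ± 0.14) and A4C (-2.05 ± 0.14) were as severe, each at least 4.15-fold lower. Of 71 tested mutations of interferon-response sites, 64 were lower and 2 were higher. Those higher were changes of CGAAAGCGAAAC between its GAAA repeats: G6T by 0.29 ± 0.14 and C7T by 0.21 ± 0.10, which turns it into the other reference site; both lost their call when every pair was tested. Averaged over the substitutions in CGAAAGCGAAAC, position 2 changed by -0.95, positions 3, 4 and 5 by -1.70, -1.74 and -1.71, positions 8 to 11 by -1.83 to -1.87, position 6 by 0.06 and position 7 by -0.99. In CGAAAGTGAAAC the averages were -0.88 at position 2, -1.26 at position 6 and -1.81 at position 7. A2G of GACCACGCCCA (0.08) and A5C of ATGCAAACAAC (0.11), at sites IRF1 did not bind, were the other rises the rule named, at intensities of 537.114 and 532.46, close to the controls; neither was called by the Mann-Whitney test.

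In FOXA2, most changes in the core of ATGTAAACAAC reduced binding to the control level, and changes at its ends had smaller effects, most of them losses. C8A lowered the intensity from 4813.91 to 2902.43, a log2 change of -0.71 ± 0.04 (SE, n = 24 and 67 spots; limma adjusted p = 1.18e-29), and G3A (-0.65 ± 0.04), A9T (-0.64 ± 0.04) and A7C (-0.63 ± 0.03) fell by similar amounts. At the ends, positions 1, 2 and 10 averaged -0.24, -0.20 and -0.16, whereas C11A (0.20 ± 0.04) and A1G (0.14 ± 0.04) were higher, and A1G was also higher by 0.14 ± 0.03 in ATGCAAACAAC. C4T, which turns ATGCAAACAAC into ATGTAAACAAC, raised the intensity by 0.36 ± 0.03. Of 40 tested mutations of forkhead sites, 27 were lower and 5 higher, and of 20 tested at other sites 0 were lower and 4 were higher (limma; 4 at unadjusted p under 0.05). The filter favoured rises, because a fall lowered the mean of its own pair. Of the reference sites printed for other families, GACCGCGCCCA alone lay above it, at a median log2 of 11.86 against 11.84. Without the filter the balance at those other sites turned, with 8 higher and 16 lower of 136. At forkhead sites 54 of 97 were then lower and 12 higher. The largest fall, -0.84 at position 3 of ATGTAAACAAC, had not passed the filter. With the further limit of 1.5-fold, 9 of the 36 calls over all sites were left.

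FOXO3A had few forkhead pairs bright enough to be tested, and limma called 0 of 29 mutations (0 at unadjusted p under 0.05 and 8 by the Mann-Whitney test). Of those 29, 5 lay at forkhead sites and 24 at other sites. ATGTAAACAAC lay just above the filter, at a median log2 of 12.48 against 12.44, so a clear fall removed its own pair. The count also hung on a few spots: 12 of 19500 had background above foreground, and without them mutations were called. When every pair was tested, 25 of 32 changes of ATGTAAACAAC were lower and 0 higher, with G3T at -0.77 ± 0.06, C8A at -0.70 ± 0.04 and C8G at -0.68 ± 0.04, sequences chosen after their values were seen. Without the filter 137 of 233 mutations were called over all sites, 36 higher and 101 lower. Across the 97 mutations of forkhead sites, the FOXO3A and FOXA2 effects correlated with r = 0.86 and rho = 0.84, each with a permutation p of 1e-05, and r was 0.84 without the 2 mutations farthest from the median.

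KLF3 showed small losses at GACCACGCCCA and large gains at a few sequences. When every pair was tested, 26 of 33 changes of GACCACGCCCA were lower and 4 higher, the largest losses being C6A at -0.36 ± 0.02 and C4T at -0.34 ± 0.02, sequences chosen after their values were seen. At GACCGCGCCCA 13 of 32 were lower and 3 higher. Calls were frequent at sites of other families too (104 of 168, against 46 of 65 at both KLF3 sites together), but their directions differed. At the KLF3 sites 39 were lower and 7 higher, and at the other sites 46 were lower and 58 higher. The filter left 3 mutations to test, and because the reference sites lay below it, rises alone could pass: C9G of GACCACGCCCA rose by 1.06 ± 0.04 to 22504 (limma adjusted p = 4.37e-52), C3T of GACCACGCCCA rose by 0.59 ± 0.03 to 15031.1, and A5G of the forkhead site ATGTAACCAAC rose by 2.31 ± 0.08, from 7000.04 to 41056.2. That last sequence, ATGTGACCAAC, was the brightest of all 627 on the KLF3 array, and 8 of its 25 spots were left without saturated or damaged ones, so the size of that rise is uncertain. Without the filter 150 of 233 mutations were called, 65 higher and 85 lower.

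**Figure D2:**
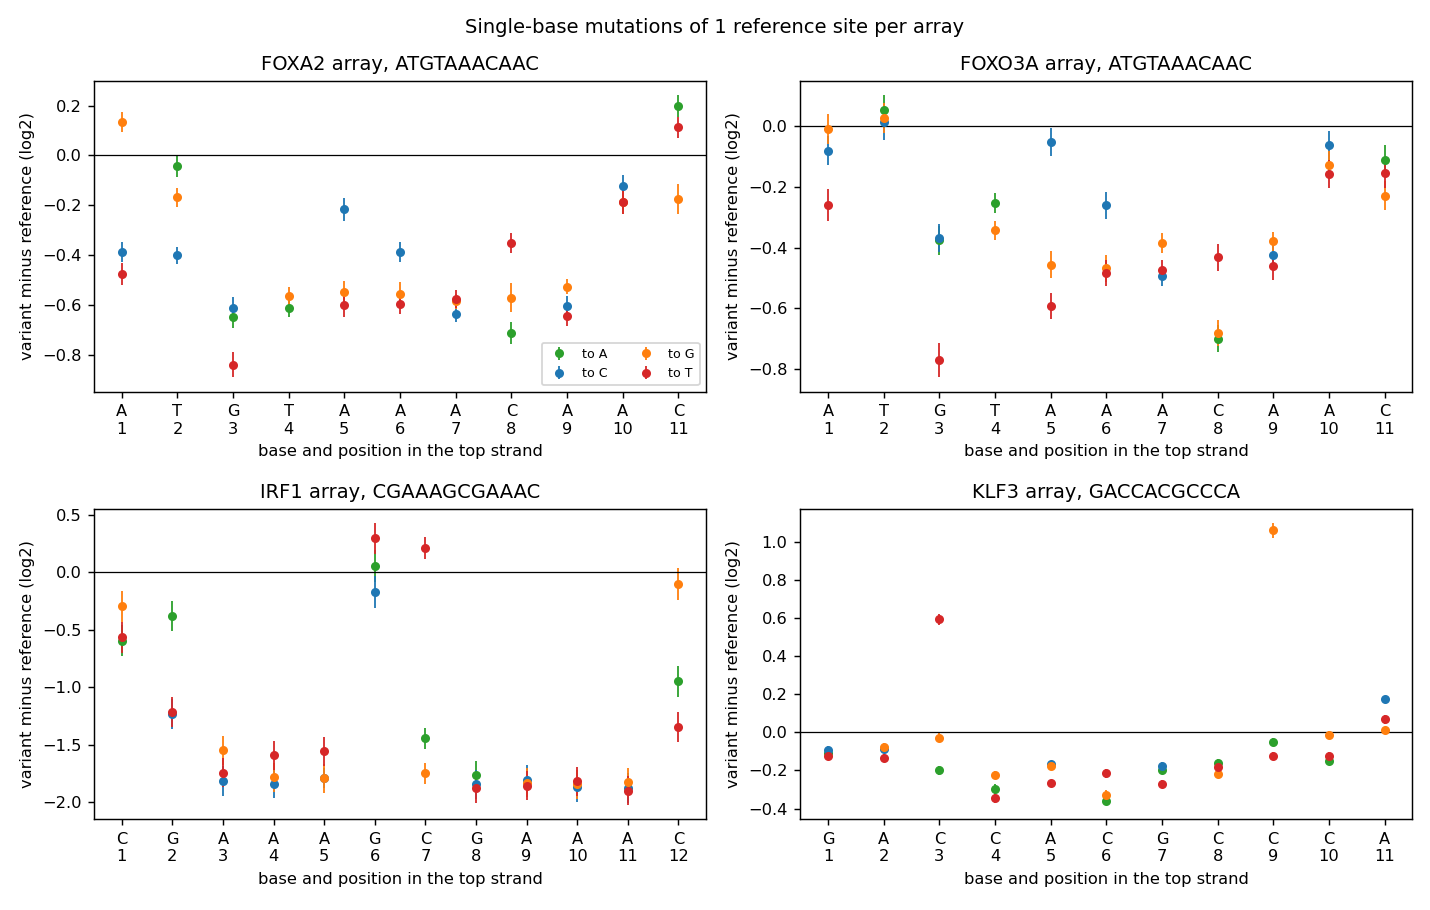
Log2 difference between each single-base variant and its reference site (points, limma estimate with standard error; colour, the new base) at each position of 1 reference site per array. Losses reached -0.84 on the FOXA2 array, -0.77 on the FOXO3A array and -1.90 on the IRF1 array, and on the KLF3 array C9G stood apart at 1.06.

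The third question was what methylcytosine outside CpG did. On the FOXA2 array it raised binding at 3 forkhead sequences in which a cytosine replaced thymine on 1 strand. Methylation of the bottom strand in ATGTAAGCAAC/GTTGXTTACAT raised the intensity from 3170.73, the level of the controls, to 6491.1, the highest value on that array, a log2 change of 0.99 ± 0.03 in intensity (SE, n = 45 and 49 spots; limma adjusted p = 3.45e-50). Because the unmethylated form did not rise above the controls, that change does not measure a fold in binding. ATGXAAACAAC rose from 3722.75 to 6171.94, by 0.75 ± 0.03 or 1.68-fold (n = 50 and 49 spots; adjusted p = 9.54e-45), and ATGCAAGCAAC/GTTGXTTGCAT rose by 0.36 ± 0.05. The methylated forms of the first 2 also exceeded ATGTAAACAAC, which holds thymine at the same base, by 0.40 ± 0.04 and 0.39 ± 0.03 (permutation p = 2e-05 each, the smallest these 2-sided permutations can give, and 3.8e-05 adjusted over 19 such comparisons). ATGTXAACAAC fell by 0.27 ± 0.05. ATGTAAACAXC changed by -0.14 ± 0.05 with an adjusted p of 0.0494, a call lost by the Mann-Whitney test and without the filter. Limma thus called 5 of 22 tested, 3 higher and 2 lower, all at forkhead sites.

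FOXO3A responded to the same bases in the same direction. ATGXAAACAAC rose from 5154.15 to 6095.57, by 0.26 ± 0.03 (SE, n = 52 and 52 spots; limma adjusted p = 3.46e-10), and was the 1 sequence called of 12 tested. It was no longer bright enough to be tested with foreground intensities, with normexp correction or with a 5 by 5 window, where its log2 differences were 0.36, 0.95 and 0.27. When every pair was tested, 11 were called, 6 higher and 5 lower; GTTGXTTACAT rose by 0.49 ± 0.03 and GTTGXTTGCAT by 0.29 ± 0.03, both chosen after their values were seen.

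IRF1 lost binding where a methylcytosine outside CpG sat at the last base pair of the site, in variants with top-strand guanine there. CGAAAGTGAAAG/XTTTCACTTTCG fell by 0.84 ± 0.15, from 1730.07 to 1050.19 (SE, n = 26 and 26 spots; limma adjusted p = 4.1e-05), and CGAAAGCGAAAG/XTTTCGCTTTCG fell by 0.73 ± 0.16. CGGAAGTGAAAC/GTTTCACTTXCG fell by 0.24 ± 0.05 and CGAGAGCGAAAC/GTTTCGCTXTCG changed by -0.10 ± 0.03, the second a call lost without the filter. Between the GAAA repeats, CGAAAXTGAAAC rose by 0.41 ± 0.12, from 974.034 to 1308.44, and the dim sequences CGAAAGTGAGAC/GTXTCACTTTCG and CGAAAGTGAAGC/GXTTCACTTTCG rose by 0.13 ± 0.04 and 0.12 ± 0.03. Of 39 tested, 3 were higher and 4 lower.

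On the KLF3 array a methylcytosine lowered the brightest sequence. The bottom-strand methylcytosine in ATGTGACCAAC/GTTGGTXACAT took the brightest sequence of that array from 41056.2 to 9029, a log2 change of -1.97 ± 0.12 (SE, n = 18 and 25 spots; limma adjusted p = 3.18e-21). The size of that loss is uncertain for the same reason, the saturated or damaged spots of the unmethylated sequence. GAXCACGCCCA rose by 0.56 ± 0.03, from 9856.88 to 15003.7, and lay at the same level as GATCACGCCCA at 15031.1 (difference -0.03 ± 0.05, permutation p = 0.535). That rise was not called with foreground intensities (0.45, adjusted p = 0.188). Those were the 2 sequences tested; without the filter 18 of 106 were called, 1 higher and 17 lower.

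The fourth question was what CpG methylation did. IRF1 binding fell with methylation of the central CpG in CGAAAGCGAAAC on either strand, and with methylation of the outer CpG of both sites on the bottom strand or on both strands. Methylation of the outer CpG on the top strand alone had a smaller estimate, called in CGAAAGTGAAAC but not in CGAAAGCGAAAC. A single methylcytosine on the top strand of the central CpG (CGAAAGXGAAAC) lowered the intensity from 1866.72 to 1065.69, a log2 change of -0.82 ± 0.07 (SE, n = 130 and 130 spots; limma adjusted p = 1.72e-26), and left 40.2% of the signal above the controls (95% interval 32.9 to 47.7%). On the bottom strand (GTTTXGCTTTCG) the change was -0.59 ± 0.08, and at the outer CpG (GTTTCGCTTTXG) it was -0.48 ± 0.09. The top strand of the outer CpG (XGAAAGCGAAAC) changed by -0.21 ± 0.09 and methylcytosine at the last base (CGAAAGCGAAAX) by -0.06 ± 0.14, and neither was called (limma adjusted p = 0.105 and 0.812). XGAAAGTGAAAC/GTTTCACTTTCG changed by -0.36 ± 0.12 (limma adjusted p = 0.0254), a call lost without the filter (adjusted p = 0.0909); these last 3 sequences were chosen after their values were seen. In CGAAAGTGAAAC, the same outer methylcytosine (GTTTCACTTTXG) gave a change of -0.66 ± 0.12. Methylation of both strands of the central CpG gave -1.07 ± 0.08, to 917.028 or 2.10-fold lower, and of the outer CpG -0.59 ± 0.10 in CGAAAGCGAAAC and -0.79 ± 0.15 in CGAAAGTGAAAC.

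The 15 correctly printed methylation states of CGAAAGCGAAAC formed a graded series. With 1 methylcytosine 40.2 to 80.7% of the signal above the controls was left, with 2 it was 20.3 to 50.4%, with 3 it was 18.0 to 27.8%, and with all 4 it was 10.7% (95% interval 8.45 to 13.8%), at an intensity of 670.393 and a log2 change of -1.50 ± 0.13. Of the 33 CpGs tested with methylation on 1 strand, 5 were lower and 0 higher (limma; 0 higher by the Mann-Whitney test), and of 18 with both strands methylated 4 were lower and 1 higher. The 1 higher, XGGTAACCAAC/GTTGGTTACXG (0.10 ± 0.04), and 1 of those lower, CGAAAXGGAAAC/GTTTCXGTTTCG (-0.06 ± 0.02), lay at control intensities and lost their calls without the filter. All 8 states of CGAAAGCGAAAC with several methylcytosines in different CpGs were lower.

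**Figure D3:**
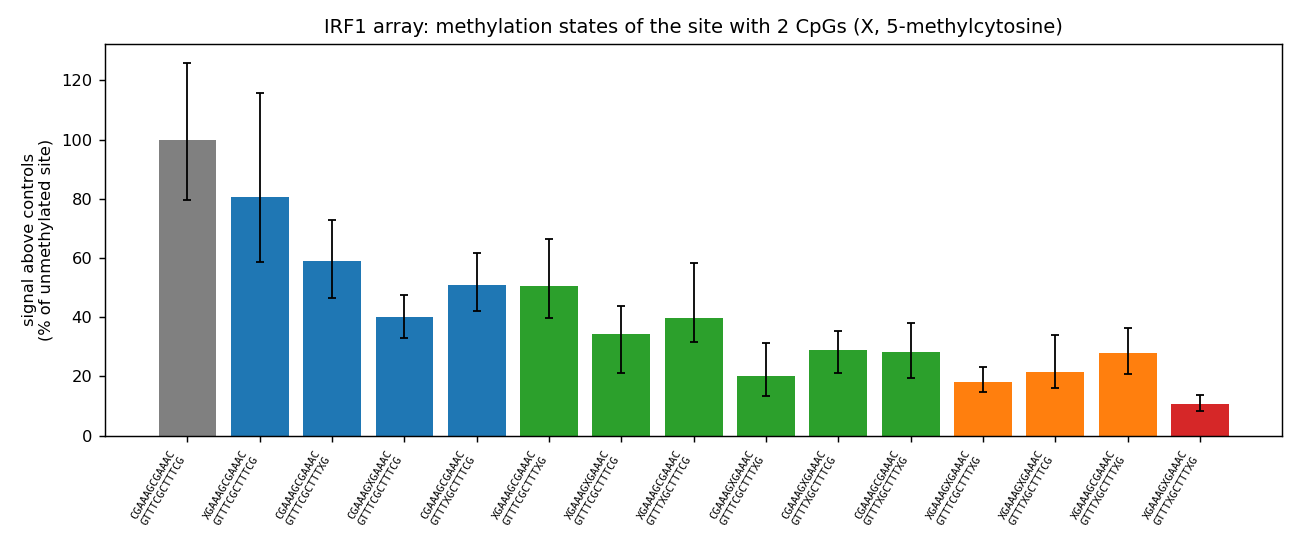
Signal above the control median on the IRF1 array for the 15 methylation states of CGAAAGCGAAAC, in percent of the unmethylated site (bars; whiskers, 95% bootstrap intervals over spots; colour, the number of methylcytosines). The share fell from 100% without methylcytosine to 10.7% with all 4.

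CpG methylation gave no call on the FOXA2 array. Limma called 0 of 37 CpGs with methylation on 1 strand (7 at unadjusted p under 0.05) and 0 of 18 with both strands methylated (1 at unadjusted p under 0.05), and the Mann-Whitney test called 0 of each. Without the filter 1 of each was called, both at the same CpG: ATGTAAACGAC/GTXGTTTACAT was higher by 0.19 ± 0.03 and ATGTAAAXGAC/GTXGTTTACAT by 0.18 ± 0.03, sequences chosen after their values were seen.

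On the FOXO3A array the changes were small. Where they lay and their balance of rises and falls depended on the filter, which passed few forkhead pairs and favoured rises. Of 34 CpGs with methylation on 1 strand 3 were higher and 1 lower, and of 12 with both strands methylated 2 were higher and 1 lower. At a forkhead site, ACGCAAACAAC/GTTGTTTGXGT changed by -0.11 ± 0.03, from 5788.74 to 5361.43 (SE, n = 26 and 52 spots, limma adjusted p = 0.0104). Methylation of the same CpG on the top strand (-0.17) or on both strands (-0.16) gave larger falls, but those pairs lay below the filter and were not tested. GACCGCGCCCG/XGGGCGCGGTC (0.10 ± 0.02), GACCGCGCCXG/XGGGCGCGGTC (0.10 ± 0.02), GACCGCGCXGA/TXGGCGCGGTC (0.09 ± 0.03), GACCGCGCCGA/TXGGCGCGGTC (0.08 ± 0.02) and GACCACGCCCG/XGGGCGTGGTC (0.08 ± 0.02) were higher, and GXGCACGCCCA/TGGGCGTGXGC was lower (-0.10 ± 0.03). The first of these turned to -0.02 with foreground intensities and to -0.12 with normexp correction, and 0 calls of either kind were left with foreground intensities or normexp correction. Without the filter 21 of 142 and 13 of 64 were called, of which 16 and 9 were lower, and most lay at forkhead sites. On 1 strand 14 of 58 were called there (12 lower and 2 higher) against 7 of 84 elsewhere. On both strands 8 of 26 were called there (6 lower and 2 higher) against 5 of 38 elsewhere.

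On the KLF3 array methylation of the CpG that C9G creates had opposite effects on its strands. GACCACGXGCA rose from 22504 to 26809.5, by 0.33 ± 0.08 (SE, n = 22 and 43 spots; limma adjusted p = 8.95e-05), whereas GACCACGCGCA/TGXGCGTGGTC changed by -0.48 ± 0.05, to 15571.8. Both calls were lost with foreground intensities (0.28 and -0.38). Limma called 0 of the 1 fully methylated CpG tested (0 at unadjusted p under 0.05; 0 by the Mann-Whitney test). Without the filter 40 of 142 CpGs with methylation on 1 strand and 30 of 64 with both strands methylated were called, of which 37 and 30 were lower. These calls were not particular to KLF3 sites. On 1 strand 13 of 40 were called there against 27 of 102 elsewhere, and on both strands 6 of 18 against 24 of 46. With both strands methylated the largest called fall was -0.19 at KLF3 sites and -0.46 elsewhere. At its own reference site, GACCAXGCCCA/TGGGXGTGGTC changed by -0.19 ± 0.02, a sequence chosen after its value was seen. Sequences with methylcytosines in several CpGs gave 0 calls by limma among 6 tested for FOXO3A and 4 for FOXA2 (0 at unadjusted p under 0.05 and 0 by the Mann-Whitney test for each), and 0 could be tested for KLF3. Without the filter 7 of 17 were called for FOXO3A and 10 of 17 for KLF3, all lower, and 0 for FOXA2 (1 at unadjusted p under 0.05). All 7 for FOXO3A lay outside forkhead sites, which had no such sequences. For KLF3 4 of 9 were called at its own sites and 6 of 8 elsewhere.

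The fifth question was whether methylation of the strands of 1 CpG added up. At the central CpG of CGAAAGCGAAAC the effect of both methylcytosines on IRF1 (-1.07) was smaller than the sum of the top (-0.82) and bottom (-0.59) effects, by 0.34 ± 0.10 on the log2 scale (limma adjusted p = 0.00585). That was 1 of 13 CpGs tested for IRF1, and it was not called with normexp correction or with a limit of 1.5-fold. Intensities included background, and the unmethylated site lay 1.82 above the control median on the log2 scale. Losses that approach this floor can look smaller than their sum. How much of the deviation came from the floor was not tested, so it does not show that the strands acted together. At the outer CpG the deviation from the sum was 0.10 ± 0.13. Limma called 0 of 16 for FOXA2, 0 of 13 for FOXO3A and 0 of 1 for KLF3, with 0 at unadjusted p under 0.05 on each; the Mann-Whitney test was not run on this contrast. Without the filter 3 were called for KLF3.

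The sixth question was whether methylcytosine acted like thymine, which carries a methyl group at the same place on the ring. Each thymine sequence also held adenine in place of guanine on the opposite strand. For FOXA2 and FOXO3A the effect of methylcytosine correlated with that of thymine at the same base more closely than with those of adenine or guanine. For KLF3 the same order held with the deposited intensities but turned with foreground intensities and in CpGs alone. For FOXO3A r was 0.65 with thymine (n = 62 positions; rho = 0.59), 0.11 with adenine and 0.095 with guanine. For FOXA2 the values were 0.52 (n = 62; rho = 0.48), -0.014 and -0.044, and for KLF3 they were 0.90 (n = 42; rho = 0.65), 0.48 and 0.43. IRF1 stood apart, with r of 0.44 for thymine (n = 46; rho = 0.54), 0.59 for adenine and 0.53 for guanine. At the central CpG of CGAAAGCGAAAC, C7T raised IRF1 binding by 0.21 ± 0.10 while methylcytosine in CGAAAGXGAAAC lowered it, and the difference between them was -1.03 ± 0.09 (permutation p = 2e-05). The C7T rise was not called without the filter.

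These correlations run across positions, which are not independent replicates. The permutation p of r with thymine was 1e-05 for FOXO3A and KLF3, 8e-05 for FOXA2 and 0.0022 for IRF1, or 6e-05, 6e-05, 0.00024 and 0.0045 after adjustment over 12 correlations, and the p of rho was 1e-05, 1e-05, 0.00012 and 0.00015. In swaps of the substitution labels, thymine exceeded adenine and guanine with p of 0.0083 and 0.023 for FOXA2, 0.0021 and 0.0022 for FOXO3A and 0.030 and 0.0009 for KLF3, but 0.951 and 0.702 for IRF1. Both effects of a position share the spots of the unmethylated sequence; simulated unchanged sequences gave r of 0.50 for FOXA2, 0.49 for FOXO3A, 0.42 for KLF3 and 0.43 for IRF1. The observed covariances of 0.020, 0.014, 0.026 and 0.134 compared with simulated ones of 0.0011, 0.00073, 0.00033 and 0.0037, and with separate reference spots r was 0.48, 0.62, 0.86 and 0.40. Without the 2 farthest positions r was 0.46 for FOXA2, 0.74 for FOXO3A, 0.75 for KLF3 and 0.41 for IRF1. With foreground intensities r for KLF3 was 0.52 with thymine and 0.61 with guanine, in CpGs alone it was 0.93 with thymine and 0.95 with adenine, and with normexp correction the label-swap permutation p was 0.324 over adenine and 0.362 over guanine (n = 42 positions). Without the 2 farthest positions that p over adenine was 0.073 for KLF3 (n = 40 positions). With foreground intensities the label-swap permutation p for thymine over adenine rose to 0.457 for KLF3 (n = 42 positions) and 0.106 for FOXO3A (n = 62 positions). In CpGs alone r was -0.031 for IRF1, and the lead of thymine over adenine and guanine had label-swap permutation p of 0.349 and 0.403 for FOXA2 (n = 14 positions) and 0.275 and 0.103 for FOXO3A (n = 14 positions). Among bound FOXA2 pairs alone, a setting added after the data were seen, that p over guanine was 0.173 (n = 22 positions).

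**Figure D4:**
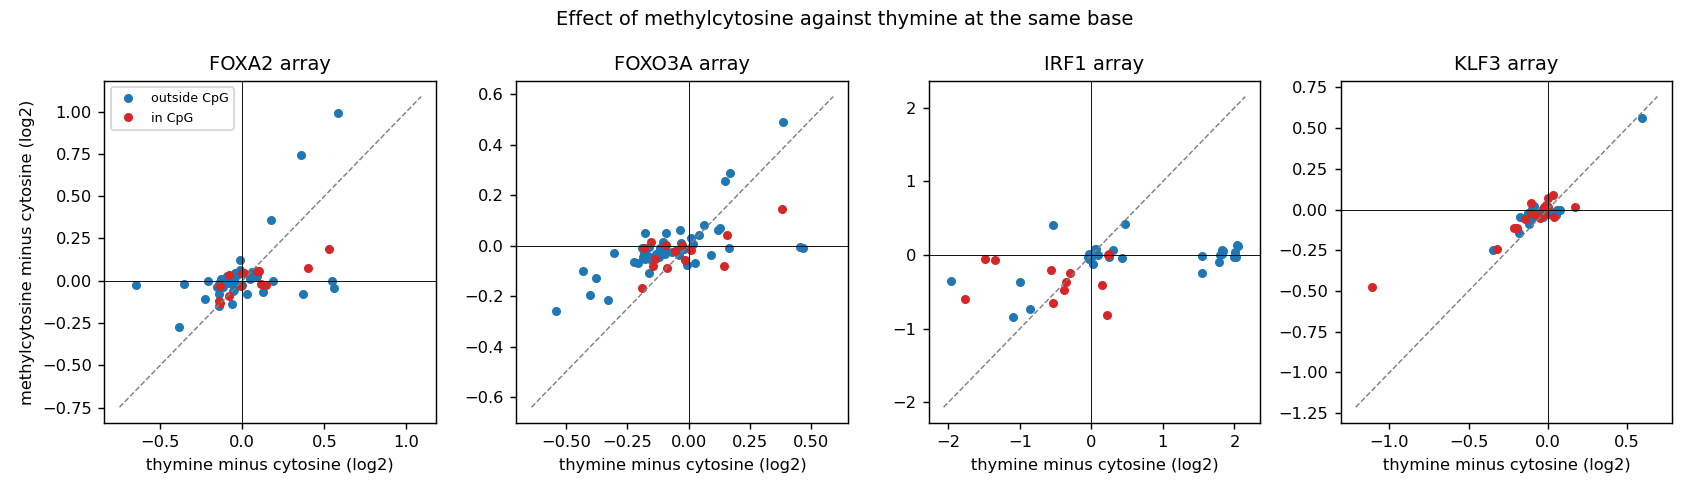
Log2 effect of methylcytosine (vertical) against that of thymine (horizontal) in place of the same cytosine, for all positions in sites of the protein's own family on each array (blue, outside CpG; red, in CpG; dashed, equal effects). Pearson r was 0.52 for FOXA2, 0.65 for FOXO3A, 0.44 for IRF1 and 0.90 for KLF3.

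The last question was whether methylation acted differently on the 2 forkhead proteins. Among the gains outside CpG, 2 were called larger on the FOXA2 than on the FOXO3A array: 0.99 against 0.49 for ATGTAAGCAAC/GTTGXTTACAT, a difference of -0.50 ± 0.05 (limma adjusted p = 3.2e-20), its unmethylated form lying at the level of the controls, and 0.75 against 0.26 for ATGXAAACAAC, a difference of -0.49 ± 0.05 (adjusted p = 1.4e-19). The other gain, in ATGCAAGCAAC/GTTGXTTGCAT, was 0.36 against 0.29, and its difference was not called. CpG methylation of ACGCAAACAAC changed the FOXO3A signal by -0.16 when both strands were methylated and by -0.17 on the top strand alone, against 0.02 and -0.03 for FOXA2, differences of -0.17 ± 0.04 and -0.14 ± 0.04. These were the 4 calls among 92 sequences tested. The last turned to 0.03 with foreground intensities, and 0 of the 4 passed the 1.5-fold limit. Across the 132 methylation effects at forkhead sites, the FOXO3A and FOXA2 values correlated with r = 0.76 and rho = 0.45 (permutation p = 1e-05 each, and 1e-05 adjusted over 3 correlations), and r was 0.59 without the 2 sequences farthest from the median. Sequences are not independent replicates, and with 1 array each, protein and array cannot be told apart.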

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

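Each test below was chosen after the result it examines had been seen, except the scaling by the mutation slope and the comparison with GC content, which were fixed earlier. The tests of brightness on the other arrays and of a label swap each replaced an earlier form that could not decide.

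The gains and losses from methylcytosine differed between the forkhead proteins: -0.50 for ATGTAAGCAAC/GTTGXTTACAT, -0.49 for ATGXAAACAAC, -0.17 for AXGCAAACAAC/GTTGTTTGXGT and -0.14 for AXGCAAACAAC/GTTGTTTGCGT, FOXO3A minus FOXA2. A narrower range of the FOXO3A array could produce this, but after the FOXA2 effects were scaled by the slope of the mutation effects (0.71, 95% interval 0.62 to 0.80), 4 of 4 differences lay beyond 2 standard errors. At the AXGCAAACAAC sequences the FOXO3A effect was the larger, which a narrower range cannot produce, so the scaling bears on the first 2 alone. For those 2 a straight-line scaling does not exclude a ceiling on high values, since the slope came from mutations that mostly lowered the signal. On the FOXO3A array their methylated forms reached 6020.59 and 6095.57, near the brightest sequence at 6450.47. The unmethylated form of the first lay at the level of the controls, so its scaled difference is uncertain. Damage or a trend in part of an array might also produce the differences, yet 4 of 4 kept their sign in the upper and the lower part. A difference between the arrays rather than the proteins was not tested, because each protein had 1 array.

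Methylcytosine outside CpG raised forkhead signals at 3 sequences. If methylated oligonucleotides were themselves brighter, the same sequences would likely rise on the other arrays, but their median effect on the IRF1 and KLF3 arrays was 0.0047. The local normalization did not create the rise, since the median rise on the FOXA2 array was 0.80 with foreground intensities. Thymine at the same bases raised the FOXA2 signal by a median of 0.36 against -0.0085 for adenine and -0.050 for guanine. Thymine there restores ATGTAAACAAC or ATGCAAACAAC, so this comparison cannot decide whether methylcytosine was read like thymine. By design each methylated sequence differed from its unmethylated form by the methyl group alone. Thymine also restored ATGTAAACAAC at positions 5, 6 and 9 of the bottom strand, raising the FOXA2 signal by 0.55, 0.56 and 0.53. Methylcytosine at those positions changed it by -0.0004, -0.041 and 0.19.

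The 10 brightest sequences on the KLF3 array held neither CACCC nor CCGCCC, the strings fixed as KLF motifs, but nor did the KLF3 reference sites, so these strings do not decide whether a KLF site was present. GC content may raise intensity, but these sequences lay a median of 0.93 above the line on GC, with a residual SD of 0.19, and on the FOX arrays the higher of the medians was 0.036. Because they were picked as the brightest on the KLF3 array, lying above the line there follows partly from that choice. Without saturated or damaged spots, 10 of 10 still exceeded the 95th percentile of the controls, although 1 sequence kept 8 spots and 2 are controls that exceed it by construction, so that 8 bear on the question. A swap of the KLF3 label with that of another array is unlikely, because mutations of ATGTAAACAAC had a median effect of 0.033 on this array (largest fall -0.17) against -0.36 for FOXO3A and -0.54 for FOXA2, and those of CGAAAGCGAAAC -0.0053 (largest fall -0.13) against -1.75 for IRF1. A swap between the FOXO3A and FOXA2 arrays was not tested. Of the 10 sequences, 6 were variants of GACCACGCCCA, and whether KLF3 or another DNA-binding protein in the sample bound them was not tested.

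Pooled PUC control spots, whose sequence was not given in the sources used here, exceeded empty spots in foreground minus background by 560 on the KLF3, 929 on the FOXO3A, 419.5 on the FOXA2 and 28 on the IRF1 array (permutation p = 1e-05 each, the smallest these permutations can give), but not in every kind: on the KLF3 array PUC2MM (-196) and PUC2PM (-177) had lower medians than empty spots (-30), and on the FOXA2 array PUC2MM (-77.5) than empty spots (-14.5).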

How the results depend on the processing

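No paired analysis was possible because each protein had 1 array. Leaving out damaged spots and splitting the arrays into an upper and a lower part were chosen after the results were seen. The normalized intensity includes background, so log2 differences are compressed and sites at the level of the controls have little signal left to lose. The filter on binding decided most counts for FOXO3A and KLF3. Of 56 named comparisons, 48 kept and 8 lost their call without the filter, 40 and 12 with the 99th percentile, 22 and 34 with the 1.5-fold limit, 47 and 5 with the 5 by 5 window, 48 and 4 by the Mann-Whitney test, 55 and 1 with a variance trend, and 48 and 4 with 1 spot per sequence left out. The 4 differences between the forkhead proteins were not run under every setting. Only 52 were therefore compared with the 99th percentile, the 5 by 5 window and the Mann-Whitney test. The same holds for 1 spot left out, damaged spots left out and the table of the whole series. With foreground intensities 31 kept, 23 lost and 2 reversed it, and with normexp correction 39 kept, 16 lost and 1 reversed it. The table of the whole series kept 52 and lost 0. Leaving out damaged spots kept 48 and lost 4, the upper part kept 33 and lost 23, and the lower part kept 42 and lost 14. Without the filter the calls for KLF3 were 150 mutations (from 3), 18 methylcytosines outside CpG (from 2), 40 CpGs methylated on 1 strand (from 2), 30 on both strands (from 0), 10 with several methylcytosines (from 0) and 3 deviations from additivity (from 0). FOXO3A then had 137 mutations (from 0), 11 outside CpG (from 1), 21 on 1 strand (from 4), 13 on both (from 3) and 7 with several methylcytosines (from 0), FOXA2 had 90 mutations (from 36), 1 on 1 strand and 1 on both strands (from 0 each), and IRF1 had 3 on both strands (from 5). With the 99th percentile, KLF3 had 1 mutation and 1 outside CpG, FOXO3A had 0 outside CpG, 1 on 1 strand, 1 on both and 0 reference sites (from 2), and FOXA2 had 1 reference site (from 3). With foreground intensities KLF3 had 5 mutations, 1 outside CpG and 0 on 1 strand, FOXO3A had 0 outside CpG, 0 on 1 strand, 0 on both and 0 reference sites, and FOXA2 had 23 mutations, 2 outside CpG (from 5) and 1 reference site; 2 differences between the forkhead proteins were left (from 4). With normexp correction FOXO3A had 0 outside CpG, 0 on 1 strand, 0 on both and 0 reference sites, FOXA2 had 2 outside CpG, 1 on 1 strand and 1 reference site, and IRF1 had 0 deviations from additivity (from 1). With the 1.5-fold limit KLF3 had 1 outside CpG and 0 on 1 strand, FOXO3A had 0 outside CpG, 0 on 1 strand and 0 on both, FOXA2 had 9 mutations and 2 outside CpG, and IRF1 had 2 outside CpG (from 7), 3 on 1 strand (from 5), 3 on both and 0 deviations from additivity; 0 forkhead differences were left. The 5 by 5 window gave 2 on 1 strand for FOXO3A and 2 for FOXA2, and the Mann-Whitney test gave 8 mutations for FOXO3A. Leaving out damaged spots gave FOXO3A 13 mutations, 8 on 1 strand and 5 on both. The upper part gave KLF3 1 outside CpG, FOXO3A 0 outside CpG and 1 on 1 strand, FOXA2 20 mutations, 3 outside CpG and 1 on both, IRF1 4 outside CpG, and 2 forkhead differences. The lower part gave FOXO3A 19 mutations, 3 outside CpG and 8 on both, FOXA2 1 on 1 strand and 2 on both, and IRF1 3 on both. The sign reversed for the IRF1 correlation with thymine in CpGs alone (-0.031), for FOXO3A at GACCGCGCCCG/XGGGCGCGGTC with foreground intensities (-0.023) and normexp correction (-0.12), and for FOXO3A minus FOXA2 at AXGCAAACAAC/GTTGTTTGCGT with foreground intensities (0.032). The cause of these changes was not tested, except that the filter and the 1.5-fold limit by construction alter which pairs can be called.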

Other observations

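On the KLF3 array, 6 of the 10 brightest sequences were variants of GACCACGCCCA, 2 were variants of forkhead sites and 2 were randomized controls; the sequences and tests in this part were chosen after the data were seen, apart from the comparison with GC content. Without the filter, a methylcytosine opposite guanine 5 lowered ATGTGAACAAC/GTTGTTXACAT from 14049.9 to 7278.74, a log2 change of -0.92 ± 0.04, and ATGCGACCAAC/GTTGGTXGCAT changed by -0.45 ± 0.03. In GACCACGCCCA, GACXACGCCCA changed by -0.25 ± 0.02. Methylation lowered 71 of 238 sequences of other families on that array without the filter and raised 0, with a median effect of -0.03. Among the 91 comparisons at KLF3 sites it lowered 23 and raised 4, with a median effect of -0.02, so the share called was about the same.

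In the IRF1 sites, methylcytosine and thymine parted at several bases. Each thymine sequence also held adenine in place of guanine on the opposite strand. For the bottom strand of the central CpG, that guanine is position 8 of the top strand, where changes averaged -1.83 for IRF1. The gap at that base therefore cannot decide whether methylcytosine and thymine were read differently. At the bottom strand of the central CpG, GTTTXGCTTTCG stayed 1.17 ± 0.06 above the sequence with thymine there, which lay at 560.264. At CGAAAXTGAAAC methylcytosine exceeded thymine by 0.95 ± 0.11.

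At position 4 on the top strand and position 7 on the bottom strand of forkhead sites, methylcytosine may give FOXA2 a stronger signal than thymine. In the same normalized intensities methylcytosine exceeded thymine by 0.40, 0.39 and 0.19 at the 3 sequences that rose, where the median thymine effect was 0.36. Thymine also carries a methyl group and pairs with adenine rather than guanine, so the excess cannot be credited to the methyl group. The excess did not extend to other bases that are thymine in ATGTAAACAAC, where methylcytosine minus thymine was -0.60 (position 6, bottom strand), -0.55 (position 5, bottom strand), -0.34 (position 9, bottom strand) and -0.33 (position 2, top strand) on the log2 scale. Titration of FOXA2 on free duplexes of ATGXAAACAAC and ATGTAAACAAC would test the difference in binding, but not which part of the base pair causes it. For IRF1 methylcytosine might not be read as thymine on the top strand of the central CpG, where it lowered binding. C7T raised binding by 0.21, but that call was lost without the filter, and C7T also replaced the opposite guanine with adenine. In CpGs alone the effects had an r of -0.031 (n = 12 positions, permutation p = 0.921), which does not show that the bases were read differently. Among them, thymine on the bottom strand of the central CpG also replaced guanine 8 and changed binding by -1.77. At the outer CpG, methylcytosine in GTTTCGCTTTXG and thymine differed by -0.09 ± 0.10. Uracil at these bases would test the part played by the methyl group of thymine. The brightest KLF3 sequences lay a median of 0.93 above the line on GC, though being picked as the brightest favours such a distance. That does not tell KLF3 from another protein in the sample. An array with a KLF3 mutant unable to bind DNA could.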
